A study of Mus musculus with 2 samples.

How the data were processed

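Total RNA of the mouse plasmacytoma line X63/0 (X63-Ag8.653), a non-secreting myeloma line of B cell origin, was compared between an untreated culture and a culture given 30 mM cycloleucine for 3 h. Cycloleucine is an amino acid analogue that inhibits methionine adenosyltransferase and thereby lowers S-adenosylmethionine (SAM). Per the labels' protocols, ribosomal RNA was depleted, the RNA was fragmented by heat, library fragments were selected by size after PCR, and sequencing was done on an Ion Proton. Per the labels' protocols, cycloleucine was added as a stock made in culture medium, and whether the untreated culture received medium alone is not given in the sources used here. The series' design text speaks of an experiment done in triplicate, and the libraries analysed here were 1 per group, 2 in all.

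The deposited table held read counts per gene, which the authors gave as total and as uniquely placed reads over genes, exons, introns and exon-exon junctions, per the file headers. It also held deposited RPKM values, reads scaled by exon length and by the library's reads, which the authors computed from those counts. Multiplying each RPKM by exon length and the library's total gene reads returned the stated reads in 43346 of 43346 features in the untreated library and in 43346 of 43346 in the cycloleucine library, within 0.02 reads plus a share of 0.0001 of them. Those reads were exon reads, or gene reads for the 13700 features without an annotated transcript. The genome build was mm10, per the submitters' processing notes, and the aligner, the counting tool, the annotation release and the use of strand are not given in the sources used here. Reads of overlapping and antisense genes may therefore not be separated. A deposited fold column equalled the signed ratio of both RPKM values in 19487 of 19487 features where both were above 0, within a share of 0.0001. The table had 0 columns of other libraries, and 5 columns of means and other summaries were not used here.

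From the deposited RPKM values, a log2 fold change was computed as the log2 of the cycloleucine value plus 0.1 over the untreated value plus 0.1, which understates the change of low genes. Features with an RPKM of at least 1 in either library and at least 50 reads over both were kept, 9613 in all, of which 9081 had an annotated transcript. With 1 library per group no test between conditions was made, and a size rule of at least 2-fold was used. Intervals are 95% exact (Clopper-Pearson) intervals of the share of a gene's reads in the cycloleucine library, scaled by library totals, or exact Poisson intervals for a single count. That of the Mat2a intron to exon ratio change is a normal approximation from its 4 counts. Counting intervals of list medians come from redrawn reads, and the intervals of the motif and short RNA medians from redrawn genes. Those from redrawn genes cover the spread between genes, and the others counting error only. None covers variation between cultures or libraries. PCR reads without molecular identifiers are not independent molecules, so the counting intervals may be too narrow. A count of 0 allows up to 3 counts, which for 1 kb of exon was 0.111 RPKM in the untreated library and 0.0939 RPKM in the cycloleucine library.

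Gene lists were fixed before the data were examined, 34 in all. The median log2 fold change of each list with at least 5 measured members was placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean expression. This percentile describes these libraries and is not a test across samples. Named genes were Mat2a and the measured members of the methionine cycle list, the 12 highest and 12 lowest log2 fold changes among genes with an RPKM of at least 5 in either library and at least 100 reads over both, up to 4 members of each other list with the largest change in either direction, and the housekeeping controls as a group. The report prints part of these. Gene models without an official symbol, nuclear genes with miRNA, snoRNA, scaRNA, snRNA or 5S rRNA symbols and marked pseudogenes were left out of the 12 and are given as a count. Mitochondrial tRNA genes were kept. A gene named outside this rule is said to be so. The result of 1 methionine cycle member is not reported here.

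Intron to exon ratios used annotated genes with at least 100 intron and 200 exon reads over both libraries, with 0.5 added to each count. Transcript GC content and 3' untranslated regions came from GENCODE M21, and 95.5% of the kept features had a GC value. The 3' untranslated region was that of the transcript with the longest coding sequence. A symbol in the table that a spreadsheet had turned into a date was found for 27 features, and these were not named. One cell, the total exon-exon reads of Mat2a in the cycloleucine library, held no number, and uniquely placed exon-exon reads were used for that gene.

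The size rule was tested on simulated data, with counts drawn from the pooled rates of the real features at the real library totals. With no true change, 0 of 9501 features passed the rule as higher and 1 as lower from counting noise. With 200 annotated genes changed for this comparison among 9518 passing features, 67 of 67 genes changed 3-fold, 66 of 66 changed 4-fold and 2 of 67 changed 1.5-fold passed. Of 400 random lists of simulated unchanged genes, 17 lay outside the middle 95% of matched lists. These simulations hold no variation between cultures or libraries.

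Alternatives fixed before the data were examined were pseudocounts of 1 and 0.01, a minimum RPKM of 5 or none, a minimum of 200 reads, rescaling to a median log2 ratio of 0, rescaling by the trimmed mean of log ratios with 30% of ratios and 5% of levels trimmed, uniquely placed reads, 5 bins of expression, and matching on gene length. A 1.5-fold threshold, annotated features alone, annotated features with over 50% unique reads, and removal of the trend with GC content were added after seeing the data. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.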

Results

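RNA-seq of rRNA-depleted total RNA was made from X63/0 mouse plasmacytoma cells without treatment and after 3 h in 30 mM cycloleucine, to follow how transcripts differ when SAM, the methyl donor made from methionine, is lowered. Each group had 1 library, so no difference described here has a replicate check and no p-value is given. The untreated library held 27127865 reads in genes and the cycloleucine library 31951946. Exon reads made up 48.4% of these in the untreated library and 49.4% in the cycloleucine library, and uniquely placed reads 64.5% and 62.97%. The feature with the most gene reads in both, Cdk8, took 7.88% of the untreated and 5.98% of the cycloleucine gene reads. Gene reads count exons and introns together, so this share is not a measure of its spliced RNA.

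Mat2a, which encodes the catalytic subunit of the SAM synthetase of most tissues, was 2.56-fold higher in the cycloleucine library (95% counting interval 2.48 to 2.64). Its RPKM was 71.2 in the untreated and 182 in the cycloleucine library, a log2 fold change of 1.35, from 5419 and 16313 exon reads. Reads across exon-exon junctions, which come from spliced RNA, were 2.58-fold higher, with 847 and 2512 uniquely placed reads (2.38 to 2.79). Intron reads of Mat2a went the other way, with 661 in the untreated and 387 in the cycloleucine library, and were 2.01-fold lower relative to all gene reads (1.77 to 2.29). The intron share of Mat2a gene reads was thus 10.9% in the untreated library (exact binomial interval 10.1% to 11.7%) and 2.32% in the cycloleucine library (2.09% to 2.56%). The gene lies on the minus strand of chromosome 6, from 72432799 to 72439558 in mm10. The authors' deposited table gave a fold of 2.56 for it.

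**Figure D1:**
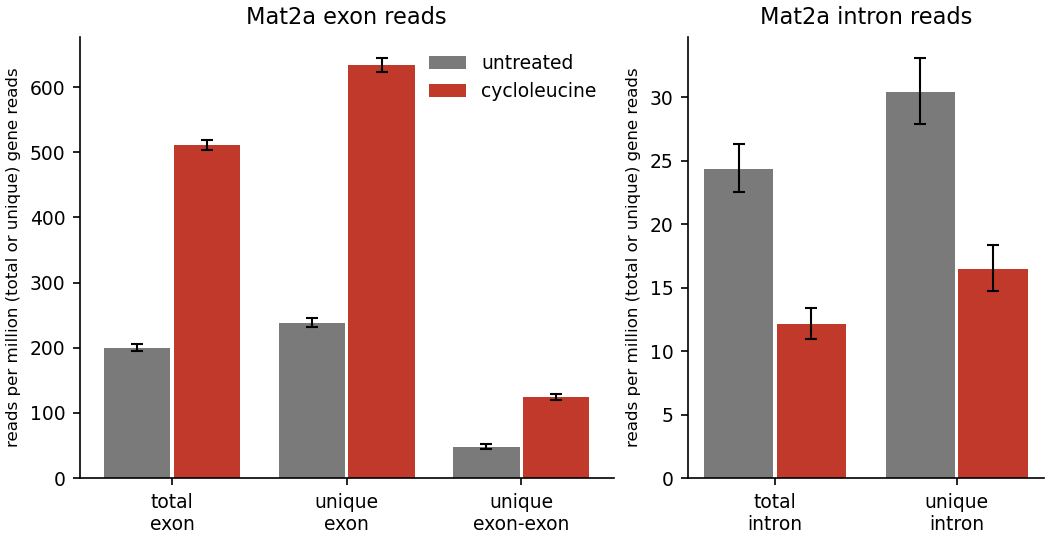
Mat2a reads, scaled to equal library totals, in the untreated (grey) and cycloleucine (red) library, with unique reads set against unique gene reads and bars for 95% exact Poisson intervals. Exon and junction reads were higher in the cycloleucine library, with 200 and 511 total exon reads on that scale, and total intron reads were lower, with 24.4 and 12.1.

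Mat2a stood apart from other annotated genes in both respects. Mitochondrial tRNA genes had no annotated transcript and are not in the sets compared here, and of these mt-Tf was at 1.43 in log2, mt-Tg at 1.28 and mt-Th at 1.24. Among 5606 annotated genes with at least 1000 reads over both libraries, 1 gene, Mat2a, was at least 2-fold higher and 2, Cpm and Vsig8, were at least 2-fold lower, while 99.3% lay within 1.5-fold. Ythdc1 fell just short of 2-fold higher by this rule, at 0.99 in log2. Its plain RPKM ratio, without the 0.1 added to each value, was 2.01. The intron to exon ratio of Mat2a had a log2 change of -2.36 (-2.55 to -2.18), the lowest of 6803 genes compared. The middle 95% of those genes lay between -0.66 and 0.72, and the next lowest was Sspn at -1.66. Ythdc1, a nuclear reader of N6-methyladenosine, had a log2 ratio change of -1.001, with 1009 and 2393 exon reads against 140 and 166 intron reads. In Rbm15, of the N6-methyladenosine writer complex, exon and intron reads were higher together and the ratio change was 0.04. In Cpm both were lower together, with 2140 and 1003 intron reads and a ratio change of -0.11.

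**Figure D2:**
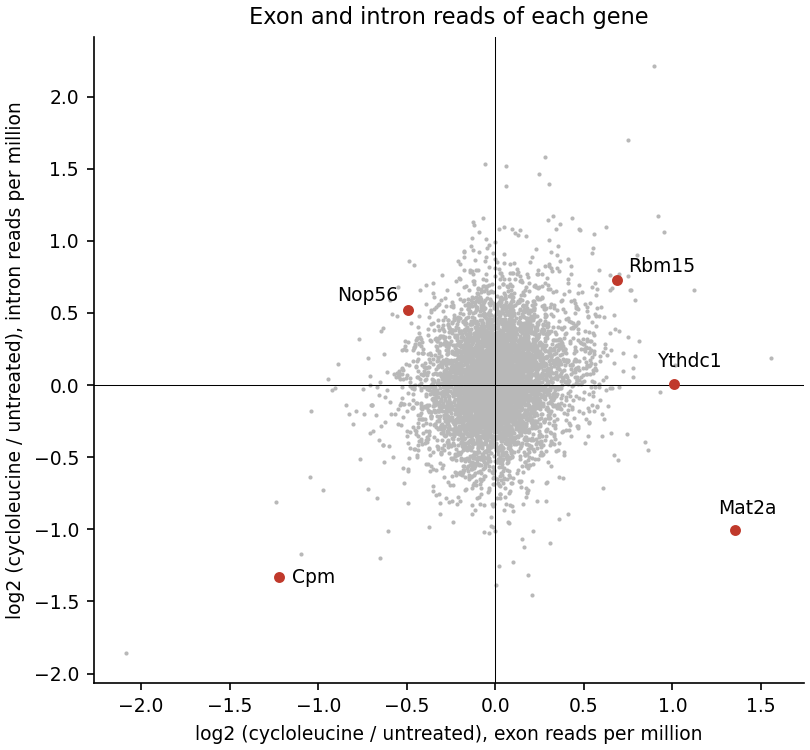
Log2 ratio of cycloleucine to untreated reads, relative to all gene reads, in exons (horizontal) and introns (vertical) for each of 6803 annotated genes. Mat2a lies alone at the lower right, with exon reads higher and intron reads lower.

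Across all kept features, 70 were at least 2-fold higher and 64 at least 2-fold lower in the cycloleucine library, and the median log2 fold change was 0.0035. Of these, 46 of the higher and 46 of the lower were gene models without an official symbol, genes with nuclear small RNA symbols or marked pseudogenes. The highest named genes were mitochondrial tRNA genes (mt-Tf 1.43, mt-Tg 1.28, mt-Th 1.24, mt-Ts1 1.09, mt-Tw 1.06, mt-Tl1 0.97 and mt-Tv 0.96 in log2), Mat2a, Rhox4a2 (1.25), Ythdc1, Adm2 and Lcmt2. Ythdc1, on chromosome 5 from 86804221 to 86836659, had an RPKM of 3.59 in the untreated and 7.23 in the cycloleucine library, a log2 fold change of 0.99 (0.90 to 1.12). Adm2, a peptide hormone gene of the calcitonin family, had a log2 fold change of 0.98 (0.67 to 1.34), and Lcmt2, an enzyme of tRNA modification that uses SAM, one of 0.94 (0.74 to 1.19). The lowest was Cpm, which encodes carboxypeptidase M, on chromosome 10 from 117629500 to 117687352, with an RPKM of 15.7 against 6.73 and a log2 fold change of -1.21 (-1.32 to -1.12). Next came Metrn at -1.09, Vsig8 at -1.03 (-1.18 to -0.89), Fam195a at -0.99, Eva1b at -0.98 (-1.26 to -0.74), Scamp4 and Hist1h2bm at -0.82, Hist1h4m at -0.78, Ighv2-6 at -0.76, the lysophospholipid transporter gene Mfsd2a at -0.70 (-0.89 to -0.53), and Fam71b and Wdr24 at -0.69. Under 2% of the reads of Rhox4a2, mt-Ts1, mt-Tw and Scamp4 were uniquely placed. From unique reads alone Vsig8 stood at -0.99, just short of 2-fold, Metrn at -0.52, Fam195a at -0.58, Hist1h4m at -0.37 and Wdr24 at -0.05. The counts were 26 higher and 19 lower with at least 200 reads, and 13 and 18 among annotated features with over 50% unique reads.

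**Figure D3:**
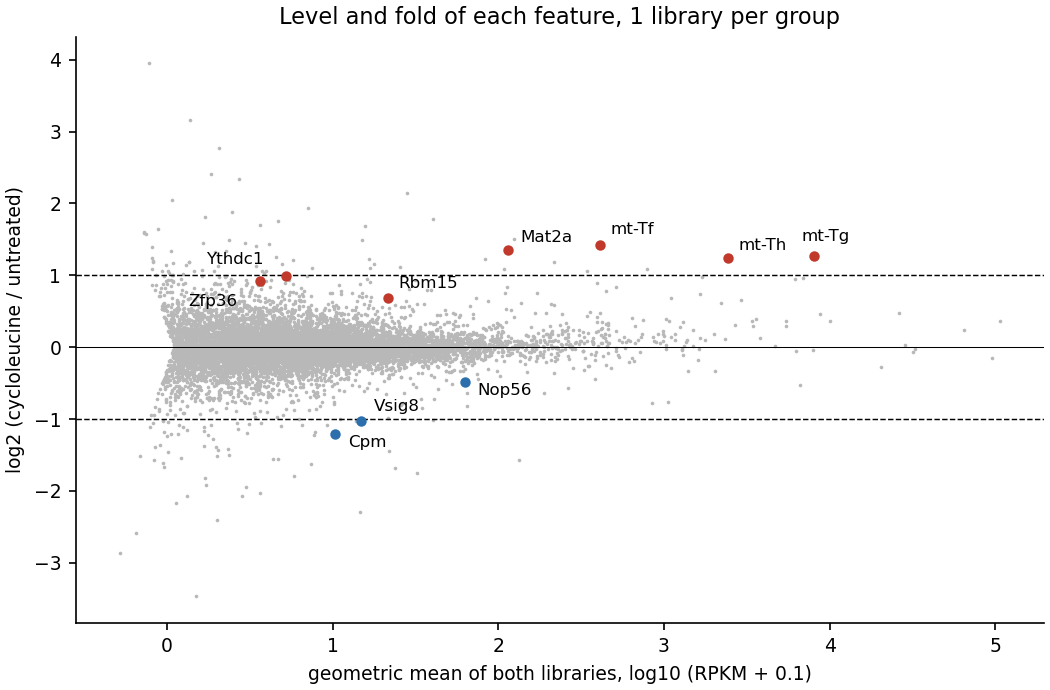
Log2 fold change of each of 9613 features against its level, the log10 of the geometric mean of both libraries' RPKM plus 0.1, with dashed lines at 2-fold. Mat2a at 1.35 and the mitochondrial tRNA genes mt-Tf, mt-Tg and mt-Th lie above the upper line at high levels, and Cpm at -1.21 and Vsig8 at -1.03 below the lower one.

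In the methionine cycle, Mat2a was the 1 gene of 11 measured that was at least 1.5-fold higher, and 6 members lay above and 5 below 0. Mat2b, the regulatory subunit of the same enzyme, was at 0.09 (-0.04 to 0.23), and the methionine synthase gene Mtr at -0.18. Ahcy, which clears S-adenosylhomocysteine, was at -0.12, Ahcyl1 at -0.18, Ahcyl2 at 0.05, Adk at -0.00041 and Mtrr at -0.07. The mitochondrial SAM carrier gene Slc25a26 was at 0.42 (0.03 to 0.86) and Cth at 0.19. The list median was 0.05, at the 77.1st percentile of matched random lists. Polyamine synthesis and methionine salvage had 17 measured members and a median of -0.0098, with Mtap at -0.32 and Oaz1 at 0.21. Serine and folate one-carbon metabolism had 16 and a median of 0.01, with Slc19a1 at -0.37 and Tyms at 0.23.

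Of 16 measured writers, erasers and readers of N6-methyladenosine, Ythdc1 and Rbm15 were at least 1.5-fold higher. Rbm15 had an RPKM of 16.8 against 27.1, a log2 fold change of 0.69 (0.60 to 0.78), while the catalytic writer gene Mettl3 was at -0.32 (-0.61 to -0.07) and Ythdc2 at -0.30. The list median was 0.05, at the 82.2nd percentile. Histone lysine methyltransferases (22 measured) had a median of -0.02, with Kmt2b at -0.25, Setd2 at 0.30 and Whsc1l1 at 0.38 (0.27 to 0.53), and DNA and protein arginine methyltransferases (12) one of -0.08, with Carm1 at -0.27 and Prmt3 at 0.16. SR proteins and CLK kinases, which act in splicing, had 15 measured and a median of -0.04. No member of these last 3 lists reached 1.5-fold in either direction.

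Of the 30 lists with a percentile, 5 lay outside the middle 95% of matched random lists, where 1.5 would be so for lists of randomly drawn genes. Members of a list can move together between cultures, so that number does not show whether 5 is unusual for these lists. Mitochondrially encoded protein genes had the highest median, 0.33, and 11 of 13 lay above 0. Immediate early genes, which respond within minutes to growth factors and stress, had a median of 0.29, at the 99.96th percentile, and 10 of 11 measured members lay above 0. The other 10 of the 21 listed were too low to measure. They include, named here outside the naming rule, Fos (8 and 10 reads), Egr1 (4 and 5) and Fosl1 (6 and 24). Among the measured members Zfp36, an mRNA decay factor, was at 0.92 (0.64 to 1.27), Dusp1, a phosphatase of MAP kinases, at 0.68 (0.32 to 1.14), Btg2 at 0.47 and Jund at 0.45. The 1 below 0, named here outside the naming rule, was Myc at -0.21, with 15679 and 16005 reads. Ribosome biogenesis genes had a median of -0.12, below all 10000 random lists, and 13 of 18 lay below 0. Nop56 was at -0.49, Rrp12 at -0.44, Gnl3 at -0.30 and Wdr43 at -0.26. The ATF4 and amino acid response list had a median of 0.10, at the 98.2nd percentile, with 11 of 18 measured members above 0 and 7 below. Nupr1 was at 0.88 (0.57 to 1.28), Ddit4 at 0.45 and Atf5 at 0.33, but Ddit3, which encodes CHOP, was at -0.69 (-0.91 to -0.48). The percentile of this list was 94.4 from unique reads. The housekeeping controls had a median of 0.13, at the 97.7th percentile, and ranged from Ppia at -0.05 to Hprt at 0.36. Their percentile was 94.3 with an RPKM of at least 5, and the median of the ATF4 list was below that of the controls.

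**Figure D4:**
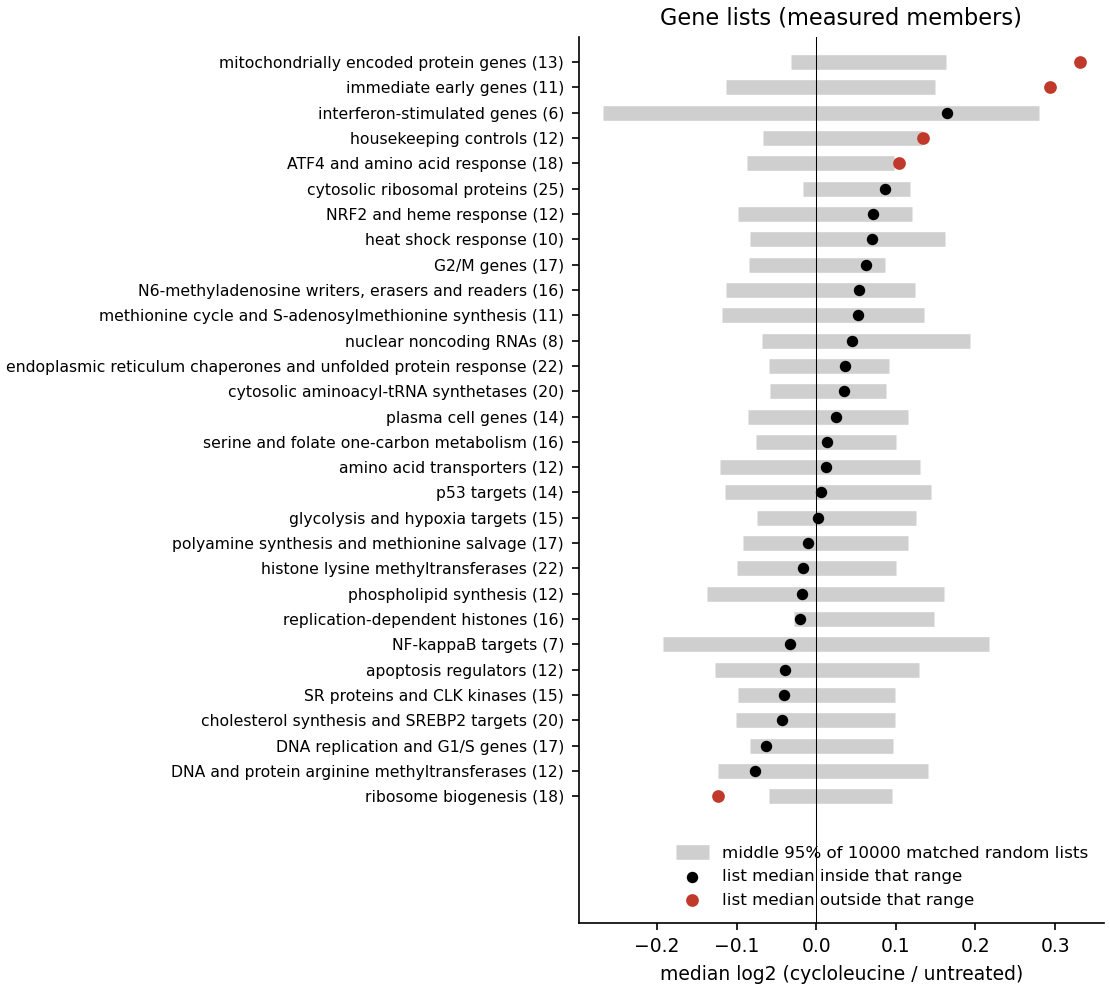
Median log2 fold change of each gene list (points, measured members in parentheses) against the middle 95% of 10000 random lists matched on expression (grey bars). Red points, such as mitochondrially encoded protein genes at 0.33 and ribosome biogenesis at -0.12, lie outside that range.

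Other stress and metabolic lists lay close to 0. Cytosolic aminoacyl-tRNA synthetases had a median of 0.04, amino acid transporters 0.01, endoplasmic reticulum chaperones 0.04, p53 targets 0.0054, NRF2 targets 0.07, heat shock genes 0.07, glycolysis and hypoxia targets 0.0024, phospholipid synthesis -0.02, NF-kappaB targets -0.03, apoptosis regulators -0.04 and nuclear noncoding RNAs 0.05. In cholesterol synthesis 14 of 20 genes lay below 0, with Mvk and Mvd at -0.61 and a median of -0.04. Among apoptosis regulators the BH3-only gene Bmf was at 0.72 (0.52 to 0.98) and Mcl1 at 0.47 (0.42 to 0.52), but Bid was at -0.37 (-0.52 to -0.22) and Casp8 at -0.29 (-0.46 to -0.13), and 7 of 12 lay below 0. DNA replication and G1/S genes had a median of -0.06, with 14 of 17 below 0 (Cdt1 -0.43 and Ccne2 -0.40, but Slbp 0.28), and G2/M genes one of 0.06, with 11 of 17 above 0. Cytosolic ribosomal proteins had a median of 0.09, replication-dependent histones -0.02 and interferon-stimulated genes 0.16 over 6 members.

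On the mitochondrial genome, 18 of 20 measured tRNA genes lay above 0, with a median log2 fold change of 0.60, and 6 were at least 2-fold higher. mt-Tf, at positions 1 to 68, had 464 and 1471 reads, and mt-Tg, at 9391 to 9458, had 9599 and 27363. The rRNA genes were not higher, with mt-Rnr1 at -0.33 and mt-Rnr2 at -0.05, and mt-Tv, which lies between them, was at 0.96. Ribosomal RNA was depleted before sequencing, so reads of the rRNA genes may also reflect how far each library was depleted, which was not tested. Among protein genes mt-Co3 was at 0.69, mt-Atp8 at 0.65 and mt-Atp6 at 0.62, while mt-Nd2 was at -0.25 and mt-Cytb at -0.10. The mitochondrial share of gene reads was 2.06% in the untreated and 2.32% in the cycloleucine library. Most reads of several of these genes were not uniquely placed, with 2.76% unique in mt-Co3 and 2.72% in mt-Atp6.

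**Figure D5:**
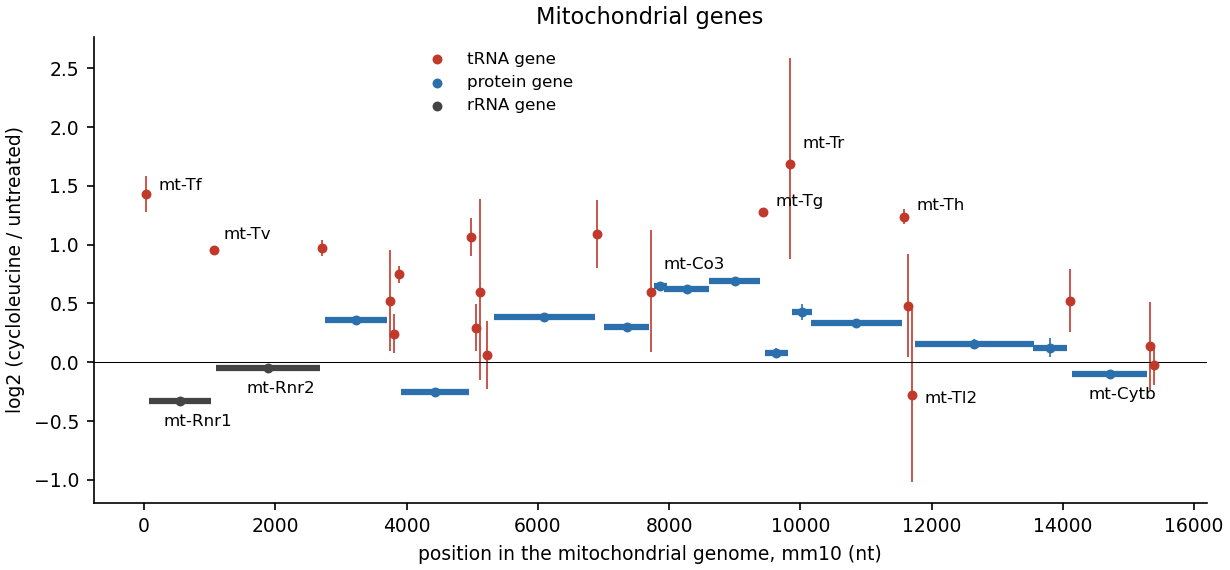
Log2 fold change of mitochondrial tRNA, protein and rRNA genes along the mitochondrial genome in mm10, with 95% counting intervals. tRNA genes such as mt-Tf at 1.43 and mt-Tg at 1.28 lie above the protein and rRNA genes next to them.

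Plasma cell genes had a median of 0.03 over 14 measured members, 10 above and 4 below 0, with Cd28 at 0.53 (0.32 to 0.81), Slamf7 at 0.35 and Tnfrsf17 at 0.33. Of B cell genes 4 were measured, Cd79b at 0.06, Ms4a1 at 0.03, Ebf1 at -0.00047 and Cd74 at -0.04. Markers of other cell types were near the floor, with no measured T and natural killer cell gene (66 and 72 reads over the list) or fibroblast gene (68 and 80 reads), and with Cd68 alone among myeloid genes, at an RPKM of 1.17 and 1.15.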

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

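The 1.5-fold threshold, both restrictions to annotated features and the removal of the GC trend were chosen after seeing the data. No paired analysis was possible because each group had 1 library, and no result here has a replicate check. Mat2a stayed at least 2-fold higher under all 5 alternatives, and the 1 value outside its counting interval was 1.41 with uniquely placed reads. The log2 change of its intron to exon ratio was -2.29 from unique reads. The number of features at least 2-fold higher and lower, 70 and 64, depended on these choices: 35 and 26 with a pseudocount of 1, 33 and 22 with an RPKM of at least 5, 1181 and 1214 with no filter, 26 and 19 with at least 200 reads, 42 and 22 with unique reads, 34 and 40 with annotated features alone, 13 and 18 with annotated and mostly unique features, 33 and 37 with the GC trend removed, and 291 and 237 at 1.5-fold. Removal of the GC trend also drops features without a GC value or an annotated transcript, so its counts compare with the 34 and 40 of annotated features. Fewer features enter under the stricter filters, and more under none.

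List medians left their counting interval in 18 of 179 alternatives, and no list outside the random range changed sign. With unique reads, whose library totals alone shift each value by 0.03, they were 0.064 for aminoacyl-tRNA synthetases, 0.074 for endoplasmic reticulum chaperones, 0.020 for histone lysine methyltransferases, 0.14 for NRF2 targets, 0.13 for heat shock, 0.055 for glycolysis, -0.020 for DNA replication, 0.37 for mitochondrial protein genes, 0.15 for ribosomal proteins, -0.086 for ribosome biogenesis, 0.081 for histones, 0.19 for housekeeping and 0.0018 for nuclear noncoding RNAs. With an RPKM of at least 5 they were -0.034 for the methionine cycle, 0.12 for N6-methyladenosine genes and 0.011 for histones. The chaperones were at 0.051 by the trimmed mean, and mitochondrial protein genes at 0.29 with the GC trend removed. The number of the 10000 random lists below a list crossed a bound in 9 of 239. For the ATF4 list it was 9647 matched on length, 9438 with unique reads and 9594 with an RPKM of at least 5. For housekeeping it was 9750 under both rescalings and 9433 with an RPKM of at least 5. For DNA replication it was 163 with the GC trend removed, and for ribosomal proteins 9846 with 5 bins and 9754 matched on length. The cause was not tested. For other named genes, 40 of 789 values left their counting interval, 29 of them with unique reads.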

Other observations

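The tests on Mat2a, the comparison within the mitochondrial genome and the intervals of the medians were chosen after the results were seen. The motif, short RNA and immediate early gene tests were set before they were run. The short RNA and immediate early gene tests address patterns already seen in these libraries, so they were not fixed before the data were examined. A few genes too low for the naming rule, and chosen after their values were seen, were at least 2-fold different with most reads uniquely placed. Ccng2, which encodes cyclin G2, had 168 and 523 reads and a log2 fold change of 1.33 (1.15 to 1.66). Klf11, a Krüppel-like transcription factor gene, had 65 and 215 reads and a log2 fold change of 1.34 (1.08 to 1.91). On the lower side Gprin1 had 278 and 145 reads (-1.10) and the copper transporter gene Slc31a2 had 59 and 20 (-1.52). These are exon reads. Intron reads went the other way in Slc31a2, with 71 and 112, and in Klf11, with 33 and 21.

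Exon and intron reads of Nop56, a box C/D snoRNP protein gene that hosts snoRNAs in its introns, moved apart in the direction opposite to Mat2a. Its exon reads were 8266 and 6926 and its intron reads 1428 and 2418, a log2 ratio change of 1.01. This gene was singled out for its introns after its values were seen.

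The higher exon reads and lower intron reads of Mat2a were weighed against technical sources. Uniquely placed reads gave a log2 fold change of 1.41, which argues against reads shared with copies of the gene, and removal of the GC trend left 1.33. A factor for a whole library moves exon and intron reads of a gene alike, and the ratio between them changed by -2.36 in log2, beyond the middle 95% of genes. How the exon reads rose while the intron reads fell was not tested, and SAM was not measured in these libraries. A difference between these 2 cultures unrelated to cycloleucine stays open, since each condition had 1 library.

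METTL16, a methyltransferase, is known to bind hairpins in the Mat2a 3' untranslated region, and the hypothesis that the same motif acts on other transcripts was tested. The Mat2a 3' untranslated region, chromosome 6 from 72432799 to 72434292 in GENCODE M21, held 6 sites, 5 of TACAGAGAA and 1 of TACAGAAAA (72433056 to 72433064). The 5 others began at 72432948, 72433167, 72433282, 72433461 and 72434245. No other gene of the 8432 kept genes with an annotated 3' untranslated region had more than 2. The 343 other genes with a site had a median log2 fold change of 0.03, at the 93.9th percentile of lists matched on expression and length of that region. The interval of that median over genes, 0.01 to 0.06, lies far below the 1.35 of Mat2a but crosses the upper bound of the random lists, 0.03, so a small shift could be neither shown nor excluded. By the condition set beforehand, a median within the middle 95% of lists, the motif would have been excluded, and the interval was added after the first run. Of the genes with a site, 273 had enough intron reads for an intron to exon ratio. The median log2 change of that ratio was 0.02, at the 72.3rd percentile of random lists. Sites were matched by sequence without structure.

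The higher mitochondrial tRNA genes could come from better recovery of short RNA in the cycloleucine library, since library fragments were selected by size. Nuclear noncoding genes of at most 150 nt, 80 in all, had a median of 0.17 against 0.60 for the tRNA genes, but the interval of that median, -0.0048 to 0.32, reaches the 0.30 that was set as the bound. The tRNA median lay at the 100th percentile of random draws of those nuclear genes. Both conditions against this explanation, set before the test was run, were thus met by the medians. Recovery of short RNA is left open only by the interval, a condition added after the first run. A rise of mitochondrial RNA as a whole is also open. The rRNA and protein genes had a median of 0.30, and the protein genes alone one of 0.33. The median of 0.30 fell short of the bound set for this explanation after the values were seen. Its interval over genes, 0.08 to 0.43, reached that bound. The rRNA genes themselves were not higher (mt-Rnr1 -0.33, mt-Rnr2 -0.05), though their reads may also reflect the depletion of ribosomal RNA. The tRNA median lay at the 96.0th percentile of random sets of mitochondrial genes. By annotated strand, 13 tRNA genes on the plus strand had a median of 0.96 and 7 on the minus strand one of 0.29, a split made after the values were seen. These explanations and an effect of cycloleucine cannot be told apart here.

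The higher immediate early genes were weighed against GC content and low counts. Among lists matched on expression and GC content the list lay at the 100th percentile, and with the 7 members of at least 500 reads at the 99.91st, with the same median of 0.29. Neither accounts for the shift of the measured members in these libraries. Immediate early genes also respond to handling and to fresh medium, and the stock was added in medium. A response to the addition itself thus stays open as a candidate explanation beside lowered SAM, and was not tested. Fos and Egr1, also on the list, were too low to measure in both libraries.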
